A study of Homo sapiens with 22 samples.

How the data were processed

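The series holds 22 libraries of polyadenylated RNA from PC9 cells and their derivatives, prepared per the labels with a directional kit after column extraction. The labels place the libraries in 11 groups of 2, named by population and treatment, and all 22 were used. The labels give a dose of 1 mM for both inhibitors and a treatment of 24 h. The dose is printed as labelled, and its unit is in doubt, since inhibitors of this kind are commonly given to cells at about 1 uM.

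Reads were aligned with STAR to hg19 and counted with HTSeq, per the submitters' processing notes, which give no versions. The strand setting of the counting is not given. The deposited values are CPM, the reads of a gene scaled to the total of its library, rounded to 2 decimals, for 17165 genes, of which 15962 carry a symbol and 1203 only an identifier. The table held 0 values equal to 0, so only genes seen in all 22 libraries are listed, and genes silent in any group were not analysed here. No genomic positions were used here.

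In each library the CPM fell on multiples of a single step, the CPM of 1 read. At least 99.994% of values in every library were whole multiples within rounding, against 23.6 to 50.4% by chance. These steps gave 23.6 to 50.4 M reads per library, of which 14.4 to 32.4 M lay in the listed genes, and the listed genes took 54.6 to 64.2% of the CPM total. The CPM were thus scaled to more reads than those of the listed genes, and the others are not described. The largest rounding error is 0.005 CPM.

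Values were taken as log2 of CPM plus a pseudocount of 1. Genes with a CPM of at least 1 in at least 2 of the 22 libraries were kept, which left 15485 genes and left out 1680. A model with 11 group means was fitted in R 4.3.3 with limma 3.58.1, with empirical Bayes moderation and a trend of the variance with the mean level, on 11 residual degrees of freedom and a median of 4.8 prior degrees of freedom. The 18 contrasts comprised 7 between treatments within a population (1 of them between the inhibitors), 6 between vehicle-treated populations and 5 differences between drug responses. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Whether responses differed between populations was taken only from the difference contrasts. Drug-treated populations were also compared with each other in 5 contrasts added after the results were seen.

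The 22 gene lists were written from general knowledge before the data were examined, as were the groups, contrasts, filter, naming rule and first alternatives. They are ERK output, EGFR family and ligands, DNA replication, mitosis, pro-apoptotic and anti-apoptotic BCL2 family, FOXO targets, epithelial, mesenchymal, other receptor kinases and ligands, drug tolerance and stem markers, cholesterol synthesis, interferon-stimulated, NF-kB and cytokines, glycolysis, integrated stress response, YAP targets, alveolar, squamous and neuroendocrine, leukocyte, endothelial and fibroblast markers, mitochondrial transcripts and handling stress. None of the 13 mitochondrial transcripts was in the table, so 21 lists were tested. Lists were tested with camera at a preset correlation of 0.01, adjusted within each contrast, and beside it with a correlation estimated from the residuals and with fry. Members were counted as passing over all genes and, beside that, after adjustment over the list alone. The list counts give tested members only. Each list call described was repeated with each library of its contrast left out in turn, in the 18 contrasts and in the 5 added ones, and the libraries are given where the call was lost.

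Genes were named by a rule: the 6 largest changes in each direction of a contrast (3 for a difference of responses) among genes with a CPM of at least 5 in a group compared, up to 3 members of each list with the lowest p, and EGFR, DUSP6, BCL2L11 and MCL1 in every contrast. Not every gene so chosen is printed. Some are not reported here. Symbols with near-identical copies (ALPP and ALPG, KRT6A and KRT14, HSPA1A) and the pseudogene SLC22A20P may hold reads from related genes.

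The fit was tested on simulated data, in 5 runs with 200 changed genes of 15485. In the comparison of GR3 with GR2 it recovered 53% of 2-fold and 89% of 4-fold changes, with 4.48% of calls wrong. In the difference of their WZ4002 responses it recovered 25.6% and 73.8%, with 4.36% of calls wrong. In each comparison all 5 changed lists and 0 of 100 unchanged lists were called, and an unchanged contrast gave 0 calls. Simulated genes varied independently and lists were random genes, whereas correlations estimated from the data reached 0.976 for mitosis and 0.488 for ERK output genes. Whether list calls hold where members vary together was therefore not shown. The SD between paired libraries was 0.105 in GR2 and 0.468 in GR3 vehicle cells, so the rates may not hold there.

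The alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, the replicate number as a block, a spread from only the groups compared and each library left out in turn. Added later were limma-voom on the recovered reads, a term for the 3 runs of columns in the table and list tests with each library left out. For the last run the term rests only on the WZ4002-treated parental and WZ4002-tolerant groups, which are split between it and the run before. Principal components were computed on all tested genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures.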

Results

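PC9 is an established human lung adenocarcinoma cell line that depends on an activated mutant EGFR, the receptor tyrosine kinase inhibited reversibly by gefitinib and irreversibly by WZ4002. Polyadenylated RNA was sequenced from 22 libraries in 11 groups of 2. Parental cells received vehicle, gefitinib or WZ4002, the derivatives PC9-GR2 and PC9-GR3 (GR2 and GR3) received vehicle or WZ4002, and cells tolerant to gefitinib or to WZ4002 received vehicle or the inhibitor named. Treatment lasted 24 h at a labelled dose of 1 mM, a unit that is in doubt. The libraries of a pair differed by more than sampling noise in every group, with a chi-square per gene of 4.185 in vehicle-treated GR2 cells and of 25.5 to 110 elsewhere, and were counted as 2 samples. The labels do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. List tests used a preset correlation between genes, and the p marked as estimated used a correlation estimated from the data. Counts of list members passing over all genes are followed in brackets by the counts after adjustment over the list alone. Counts of 0 to 3 members against the direction of a list moved by at most 2 when single libraries were left out. Levels are given as mean CPM ± SD (n = 2) and changes as log2 differences ± SE of CPM plus a pseudocount of 1, a scale that understates the change of low genes.

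The 1st principal component held 54.8% of the variance and ran from vehicle-treated to drug-treated libraries in each population. The 2nd, with 16.4%, ran from parental and GR2 cells to tolerant cells. The 3rd, with 11.9%, set the 4 GR3 libraries, at 38.0 to 38.8, apart from all others, at or below -1.17.

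**Figure D1:**
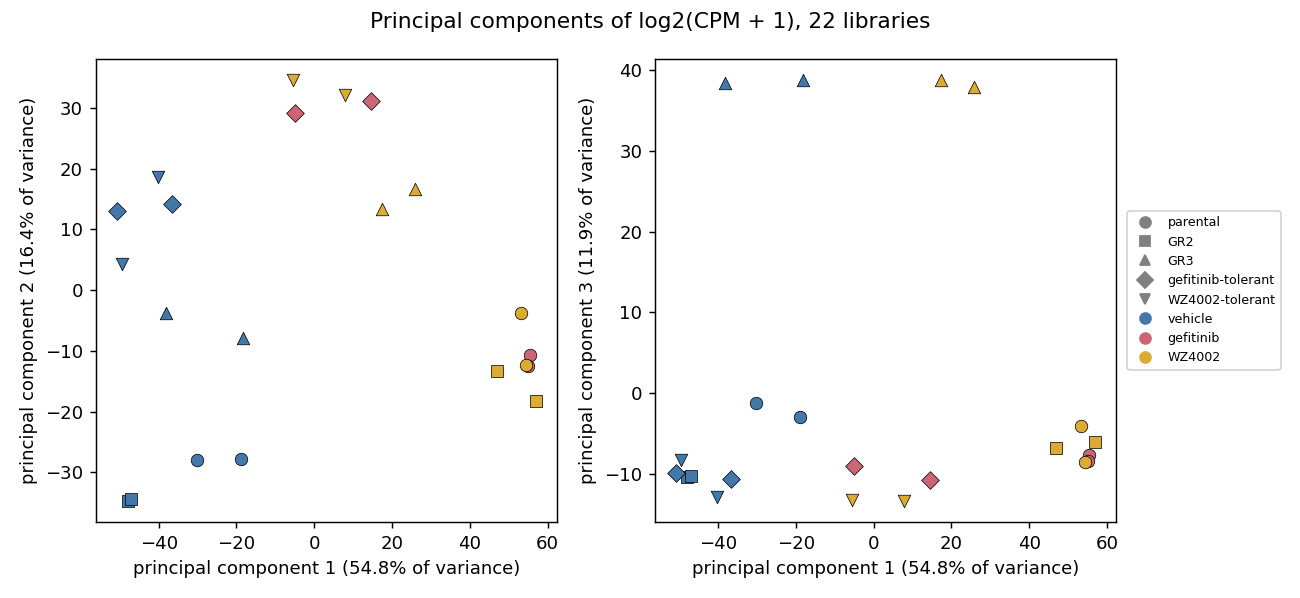
Principal components of log2(CPM + 1) over the 22 libraries, with component 1 (54.8% of the variance) on the x axis against component 2 (16.4%, left) and component 3 (11.9%, right); each point is a library, its shape gives the population and its colour the treatment. Parental libraries lie at -30.2 and -18.8 on component 1 after vehicle and at 53.3 to 55.4 after either drug, whereas gefitinib-tolerant libraries lie at -5.03 and 14.5 after gefitinib.

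The parental response to gefitinib gives the transcript changes of the starting population after 24 h, direct and indirect ones together. DUSP6, a phosphatase that inactivates ERK, fell from 107 ± 5.11 to 0.345 ± 0.00707 CPM (-6.32 ± 0.41, adjusted p = 1.23e-07). Of the 18 ERK output genes, 17 fell (17, median -2.84, list adjusted p = 4.86e-12, 0.172 estimated), among them the transcription factors ETV5 (-5.90 ± 0.38) and ETV4 (-4.89 ± 0.31). The feedback inhibitor SPRY4 (-4.99 ± 0.44), the interleukin-33 receptor IL1RL1 (-5.48 ± 0.26) and the integrin ITGA6 (-4.77 ± 0.35) fell as far. The largest rises were in the keratin KRT4 (6.18 ± 0.54), the placental alkaline phosphatase ALPP (6.001 ± 0.55), the proton pump subunit ATP6V1B1 (5.74 ± 0.50), the death ligand TNFSF10 (4.98 ± 0.37) and the p53 target TP53INP1 (4.90 ± 0.47). ALPP and its neighbour ALPG are near-identical copies, so both are uncertain.

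Cell cycle genes fell with gefitinib. Of 21 DNA replication genes 20 fell (20, median -2.29, adjusted p = 2.75e-11, 0.31 estimated). The licensing factor CDC6 (-3.67 ± 0.35) and the helicase subunit MCM7 (-1.93 ± 0.22) were among them. All 20 mitosis genes fell (20, median -2.45, adjusted p = 6.74e-07, 0.5 estimated). The kinase CDK1 (-3.27 ± 0.65) was among them. Of 12 integrated stress response genes 8 fell (8, median -1.67, adjusted p = 4.9e-05, 0.283 estimated), led by the serine and asparagine synthesis enzymes PSAT1 (-4.06 ± 0.30) and ASNS (-4.03 ± 0.42). Of 14 glycolysis genes 10 fell and 0 rose (11 and 1, median -0.95, adjusted p = 0.000729, 0.5 estimated). Without the 1st vehicle library 13 mitosis and 5 glycolysis genes fell.

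The other 5 lists that passed had medians above 0. Of 13 FOXO target genes 9 rose and 0 fell (9 and 1, median 1.69, adjusted p = 0.000504, 0.185 estimated). PIK3IP1, an inhibitor of PI3K (4.62 ± 0.46), and the insulin receptor INSR (1.80 ± 0.20) were among them. Of 15 epithelial genes 10 rose and 1 fell (10 and 1, median 0.58, adjusted p = 0.0012, 0.172 estimated). The tight junction protein CLDN3 (2.12 ± 0.28) and the keratin KRT8 (1.22 ± 0.16) were among them. Of 14 cholesterol synthesis genes 11 rose (12, median 1.12, adjusted p = 0.000974, 0.55 estimated). The count was 7 and 5 without the 1st and the 2nd gefitinib library and 6 without either vehicle library. Of 13 interferon-stimulated genes 5 rose and 0 fell (9 and 1, median 0.66, adjusted p = 0.0115, 0.5 estimated). IFIT2 (2.07 ± 0.24) was among them. Of 6 squamous and neuroendocrine genes 5 rose (5, median 1.51, adjusted p = 0.0115, 0.172 estimated). Those named were the basal keratins KRT5 (2.08 ± 0.33) and KRT6A (1.73 ± 0.22), the latter uncertain because it has near-identical copies.

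In all, 7017 of 15485 genes passed in limma (3635 higher and 3382 lower), 2571 of them by at least 2-fold. Without the 1st parental vehicle library the count was 4525. The other 11 lists gave adjusted p of 0.082 to 0.963: EGFR family and ligands (median 0.07), pro-apoptotic BCL2 family (0.13), anti-apoptotic BCL2 family (-0.55), mesenchymal genes (0.02), other receptor kinases and ligands (0.51), drug tolerance and stem markers (0.39), NF-kB and cytokine genes (0.04), YAP targets (0.54), alveolar genes (0.21), leukocyte, endothelial and fibroblast markers (0.18) and handling stress genes (0.06).

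WZ4002 gave parental cells a response of like extent. DUSP6 fell to 0.435 ± 0.00707 CPM (-6.23 ± 0.41, adjusted p = 1.53e-07), ETV5 by -5.94 ± 0.38 and IL1RL1 by -5.68 ± 0.26. KRT4 (6.14 ± 0.54), ATP6V1B1 (5.88 ± 0.50), TNFSF10 (5.09 ± 0.37) and the autophagy gene ATG9B (5.17 ± 0.72) rose. By list, 17 of 18 ERK output genes (17, median -2.88, adjusted p = 1.84e-11, 0.19 estimated), 20 of 21 DNA replication genes (20, median -2.16, adjusted p = 5.45e-10, 0.375 estimated) and 19 of 20 mitosis genes (19, median -1.94, adjusted p = 4.44e-05, 0.619 estimated) fell. Without the 1st WZ4002 library the mitosis median was -1.15 and 0 members passed, and 1 passed without the 1st vehicle library. Of 12 integrated stress response genes 9 fell (10, median -2.17, adjusted p = 5.73e-06, 0.19 estimated), including PSAT1 (-3.82 ± 0.30), and 11 of 14 glycolysis genes fell (11, median -0.94, adjusted p = 0.000174, 0.48 estimated). FOXO targets rose in 10 of 13 members and fell in 1 (10 and 1, median 1.53, adjusted p = 0.000732, 0.19 estimated), epithelial genes rose in 10 of 15 and fell in 1 (10 and 1, median 0.55, adjusted p = 0.00615, 0.19 estimated), and squamous and neuroendocrine genes rose in 4 of 6 (4, median 1.29, adjusted p = 0.025, 0.19 estimated). Without the 2nd WZ4002 library 6 epithelial genes rose. The calls of interferon-stimulated genes (adjusted p = 0.0227) and YAP targets (adjusted p = 0.0415), each with adjusted p = 0.584 with an estimated correlation, were lost without the 2nd WZ4002 library (0.0611 and 0.121), the latter also without the 2nd vehicle library (0.071). In all, 7348 genes passed (3892 higher and 3456 lower), 2651 by at least 2-fold, and 4840 passed without the 1st parental vehicle library.

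The inhibitors were compared directly in parental cells at the same labelled dose and time. DUSP6 differed by 0.09 (95% interval -0.79 to 0.97, WZ4002 minus gefitinib), EGFR by 0.19 (-0.33 to 0.71), BCL2L11 by -0.17 (-0.55 to 0.22) and MCL1 by -0.21 (-0.49 to 0.06), each with an adjusted p of 0.999. The sign of the DUSP6 difference turned with a term for runs of columns in the table (-0.12), and that of EGFR turned without the 2nd gefitinib library (-0.03) or the 2nd WZ4002 library (-0.08). By limma 0 genes passed, 525 had an unadjusted p under 0.05, and limma-voom on recovered reads also called 0 genes. The 95% interval excluded a log2 difference of 1 for 92.6% of genes. Low genes such as DUSP6 can differ 2-fold within it, so equality was not shown. Without the 1st WZ4002 library 343 genes passed. The largest list difference was in cholesterol synthesis, where 0 of 14 members passed over all genes and 12 were lower after WZ4002 adjusted over the list alone (median -0.91, adjusted p = 6.57e-17, 0.49 estimated). Without the 2nd WZ4002 library the median was -0.13 and the list adjusted p was 0.174, and without the 1st it was -1.63 with 14 of 14 members passing. Mitosis genes had a median of 0.61 (adjusted p = 0.0102, 0.89 estimated), which gave an adjusted p of 0.679 without the 2nd gefitinib library and a median of -0.33 (adjusted p = 0.0622) without the 2nd WZ4002 library, against 0.96 and 1.496 without the 1st library of either.

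WZ4002 in GR2 cells gave the largest number of changed genes of any drug response. DUSP6 fell from 271 ± 6.60 to 0.945 ± 0.488 CPM (-7.15 ± 0.41, adjusted p = 7.29e-09), and FOSL1, an AP-1 subunit (-6.18 ± 0.66), the EGFR ligand HBEGF (-6.16 ± 0.51) and the collagen COL8A1 (-6.05 ± 0.35) fell with it. VTCN1, an immune checkpoint ligand, rose from 0.570 ± 0.325 to 407 ± 76.4 CPM (8.02 ± 0.53), beside the FOXO-induced DEPP1 (6.21 ± 0.36) and the semaphorin SEMA5A (6.19 ± 0.40). The mucin MUC1 rose by 5.61 ± 0.33 among the alveolar genes, of which 5 of 8 rose (5, median 0.72, adjusted p = 0.0185, 0.261 estimated). Without the 1st vehicle-treated or the 2nd WZ4002-treated GR2 library 3 rose.

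By list, 16 of 18 ERK output genes fell in GR2 cells (16, median -3.26, adjusted p = 2.18e-09, 0.261 estimated), as did 20 of 21 DNA replication genes (20, median -2.26, adjusted p = 3.88e-07, 0.509 estimated). Mitosis genes fell in 19 of 20 members (19, median -2.05, adjusted p = 0.000487, 0.633 estimated). Without the 2nd WZ4002-treated GR2 library the median was -1.30 and 2 members passed, and 12 passed without the 1st vehicle library. Integrated stress response genes fell in 10 of 12 (10, median -2.42, adjusted p = 4.03e-05, 0.261 estimated), including ASNS (-5.38 ± 0.42) and the cystine transporter SLC7A11 (-4.91 ± 0.43), and glycolysis genes fell in 10 of 14 and rose in 1 (11 and 1, median -1.08, adjusted p = 0.00786, 0.627 estimated). FOXO targets rose in 9 of 13 and fell in 3 (9 and 3, median 1.93, adjusted p = 0.00543, 0.272 estimated). PIK3IP1 (6.06 ± 0.46) was among them. Epithelial genes rose in 10 of 15 and fell in 1 (11 and 2, median 0.70, adjusted p = 0.00245, 0.261 estimated). Cholesterol synthesis genes rose in 11 of 14 (11, median 1.32, adjusted p = 0.00543, 0.633 estimated) and interferon-stimulated genes in 7 of 13 (7, median 0.94, adjusted p = 0.0106, 0.523 estimated). In all, 8618 genes passed (4238 higher and 4380 lower), 3644 by at least 2-fold, and 6925 passed with the column-run term, both GR2 vehicle libraries being in the last of 3 runs of columns.

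In GR3 cells WZ4002 lowered DUSP6 from 46.0 ± 15.3 to 0.200 ± 0.170 CPM (-5.26 ± 0.41, adjusted p = 1.65e-06; -7.96 for DUSP6 in GR3 WZ4002 response by limma-voom on recovered reads). ETV5 (-5.79 ± 0.38), ETV4 (-4.72 ± 0.31), SPRY4 (-4.98 ± 0.44) and the collagen COL13A1 (-4.11 ± 0.28) also fell. ATP6V1B1 (4.07 ± 0.50), the aminotransferase AGXT (3.95 ± 0.63) and SEMA5A (3.49 ± 0.40) rose. Of 18 ERK output genes 15 fell and 1 rose (16 and 1, median -2.76, adjusted p = 1.26e-15, 0.137 estimated), and 10 of 12 integrated stress response genes fell (11, median -1.88, adjusted p = 4.39e-09, 0.137 estimated). PSAT1 (-2.94 ± 0.30) and SESN2 (-2.71 ± 0.31) were among them. FOXO targets rose in 8 of 13 (9 higher and 1 lower, median 0.98, adjusted p = 0.00284, 0.267 estimated). Without the 1st vehicle library 3 rose, and 4 without the 1st (median 0.61) or the 2nd WZ4002-treated GR3 library. Epithelial genes rose in 8 of 15 (9 higher and 2 lower, median 0.49, adjusted p = 0.00125, 0.137 estimated). Without the 1st vehicle library 5 rose. Interferon-stimulated genes rose in 5 of 13 (6, median 0.63, adjusted p = 0.00679, 0.43 estimated). Cholesterol synthesis genes rose in 7 of 14 (12, median 0.96, adjusted p = 9.1e-05, 0.43 estimated). The count was 1 without the 2nd vehicle library (median 0.55), 2 without the 1st and 1 without the 2nd WZ4002 library. Lost without the 1st vehicle library were the calls of DNA replication (adjusted p = 2.63e-06, then 0.0781), mitosis (0.000487, then 0.0908) and YAP targets (0.0331, then 0.1), the latter 2 also without the 2nd WZ4002 library (0.296 and 0.279). Those of EGFR family and ligands (0.049) and other receptor kinases and ligands (0.0423) were lost without the 2nd vehicle (0.385 and 0.159) or the 1st WZ4002 library (0.0738 and 0.177). These 5 lists had an adjusted p of 0.398 to 0.584 with an estimated correlation. In all, 3406 genes passed (1878 higher and 1528 lower), 1175 by at least 2-fold; 1987 passed without the 1st vehicle-treated GR3 library, 1729 without the 2nd WZ4002-treated one and 693 with a spread estimated from these 4 libraries alone.

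Gefitinib in gefitinib-tolerant cells lowered DUSP6 from 27.4 ± 0.962 to 2.65 ± 2.17 CPM (-3.10 ± 0.41, adjusted p = 0.000293). SPRY4 (-3.23 ± 0.44), ETV5 (-3.14 ± 0.38), the chromatin protein HMGA2 (-2.98 ± 0.40) and the neurotensin receptor NTSR1 (-2.83 ± 0.32) fell. ALPP (4.39 ± 0.55), the water channel AQP3 (3.60 ± 0.60), the amino acid transporter SLC7A7 (3.27 ± 0.52) and BMF, a pro-apoptotic BH3-only gene (3.14 ± 0.48), rose. Of 18 ERK output genes 16 fell (18, median -1.82, adjusted p = 2.72e-11, 0.282 estimated), and 10 of 21 DNA replication genes fell (11, median -0.95, adjusted p = 5.84e-05, 0.526 estimated). FOXO targets rose in 9 of 13 members and fell in 1 (9 and 2, median 1.011, adjusted p = 0.000381, 0.282 estimated). Interferon-stimulated genes rose in 8 of 13 (8, median 0.97, adjusted p = 0.000117, 0.341 estimated) and glycolysis genes fell in 5 of 14 (12 lower and 1 higher, median -0.71, adjusted p = 0.00147, 0.526 estimated). Most of these counts fell when single libraries were left out. Without the 2nd gefitinib-treated library 8 ERK output, 0 DNA replication, 5 FOXO target, 4 interferon-stimulated and 0 glycolysis genes passed. Without the 1st vehicle-treated library the last 4 counts were 0, 5, 4 and 0, and without the 2nd 5 DNA replication and 2 glycolysis genes passed. The call of cholesterol synthesis (adjusted p = 0.0106, 0.7 estimated) was lost without the 1st gefitinib-treated library (0.0569). In all, 4446 genes passed (2346 higher and 2100 lower), 1182 by at least 2-fold. Without the 1st vehicle-treated or the 2nd gefitinib-treated library of these cells 985 and 976 passed.

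WZ4002 in WZ4002-tolerant cells lowered DUSP6 from 27.0 ± 13.2 to 2.39 ± 1.95 CPM (-3.09 ± 0.41, adjusted p = 0.000223), together with HMGA2 (-3.87 ± 0.40), IL1RL1 (-3.47 ± 0.26), SPRY4 (-3.34 ± 0.44), NTSR1 (-3.29 ± 0.32) and the hyaluronan synthase HAS3 (-2.98 ± 0.26). SLC7A7 (3.52 ± 0.52), PIK3IP1 (3.29 ± 0.46), AQP3 (3.18 ± 0.60) and the stress-induced NUPR1 (3.17 ± 0.60) rose. ERK output genes fell in 12 of 18 members (12, median -1.35, adjusted p = 7.16e-07, 0.394 estimated) and DNA replication genes in 15 of 21 (19, median -1.19, adjusted p = 9.12e-07, 0.522 estimated). Without the 1st vehicle-treated and the 1st WZ4002-treated library 2 and 3 DNA replication genes fell. FOXO targets rose in 8 of 13 and fell in 1 (8 and 1, median 0.84, adjusted p = 0.000384, 0.394 estimated). Calls of mitosis, pro-apoptotic BCL2 family, cholesterol synthesis, interferon-stimulated, NF-kB and cytokine and glycolysis genes had adjusted p of 0.0137 to 0.0173 (0.394 to 0.709 estimated). Each was lost without at least 1 of the 1st vehicle-treated and the 1st and the 2nd WZ4002-treated library. In all, 5049 genes passed (2638 higher and 2411 lower), 1290 by at least 2-fold. Without the 1st vehicle-treated or the 1st WZ4002-treated library of these cells 1401 and 2999 passed.

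**Figure D2:**
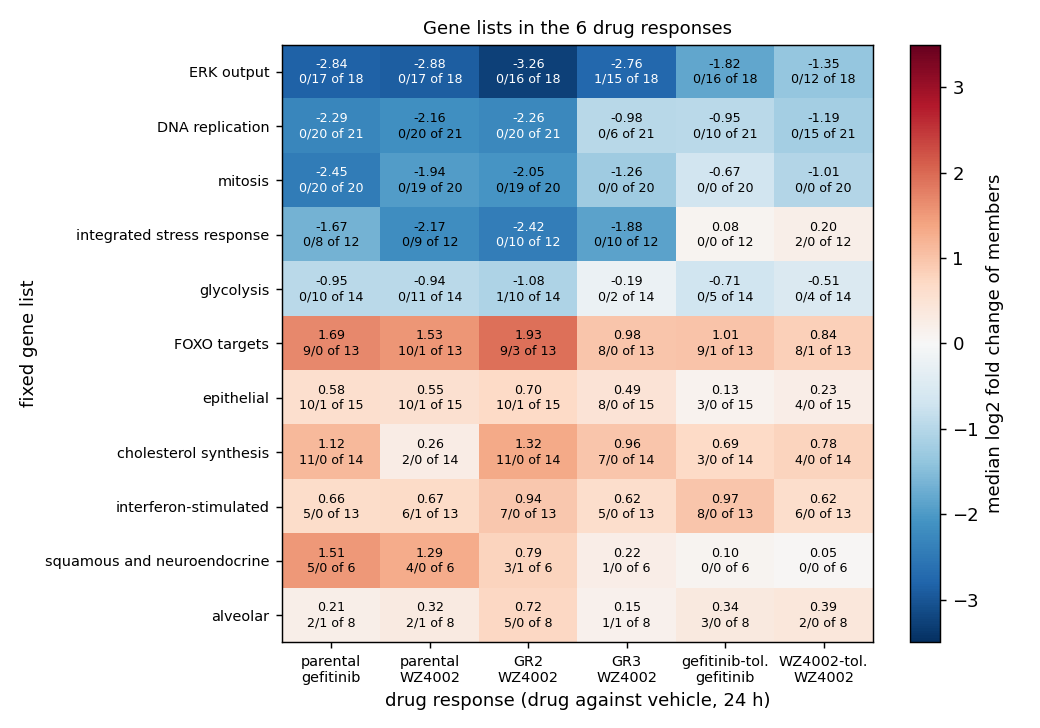
Median log2 change of CPM plus 1 (colour, drug against vehicle) for 11 gene lists (y axis) in the 6 drug responses (x axis), with the members higher and lower out of those tested written in each cell. ERK output genes have medians of -2.84 to -3.26 in the parental and GR2 responses, -2.76 in GR3 cells, and -1.82 and -1.35 in gefitinib-tolerant and WZ4002-tolerant cells.

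BCL2L11, which encodes the pro-apoptotic protein BIM, was followed across the populations. Under drug it rose in parental cells from 17.9 ± 1.05 to 53.1 ± 5.87 CPM with gefitinib (1.51 ± 0.18, adjusted p = 1.48e-05) and to 47.3 ± 7.46 with WZ4002 (1.35 ± 0.18, adjusted p = 3.52e-05), and in GR2 cells from 12.8 ± 0.665 to 79.4 ± 5.90 (2.54 ± 0.18, adjusted p = 3.2e-08). In GR3 cells it stood at 25.0 ± 7.68 before and 32.4 ± 3.54 CPM after WZ4002 (0.39 ± 0.18, adjusted p = 0.131; 0.69 with adjusted p = 0.0123 without the 2nd vehicle-treated GR3 library). In gefitinib-tolerant cells it rose from 21.2 ± 0.0566 to 36.9 ± 0.792 CPM (0.77 ± 0.18, adjusted p = 0.0058), a call lost without the 2nd gefitinib-treated (adjusted p = 0.0507) or the 1st vehicle-treated library (adjusted p = 0.0573). In WZ4002-tolerant cells it rose from 23.2 ± 0.552 to 37.4 ± 7.46 CPM (0.65 ± 0.18, adjusted p = 0.0127), a call lost without the 1st vehicle-treated (adjusted p = 0.089) or the 1st WZ4002-treated library (adjusted p = 0.135). The rise under WZ4002 differed between GR3 and GR2 cells by -2.15 ± 0.25 (adjusted p = 9.01e-05). Against the parental rise the difference passed in GR2 cells (1.19 ± 0.25, adjusted p = 0.0107; adjusted p = 0.279 with the column-run term and 0.0594 without the 1st GR2 vehicle library). It did not pass in GR3 cells (-0.96 ± 0.25, adjusted p = 0.073; adjusted p = 0.00937 without the 1st GR3 vehicle library and 0.033 with the column-run term), in gefitinib-tolerant cells (-0.74 ± 0.25, adjusted p = 0.156; adjusted p = 0.0468 from the groups compared alone) or in WZ4002-tolerant cells (-0.69 ± 0.25, adjusted p = 0.129), so a smaller rise than in parental cells was not shown.

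**Figure D3:**
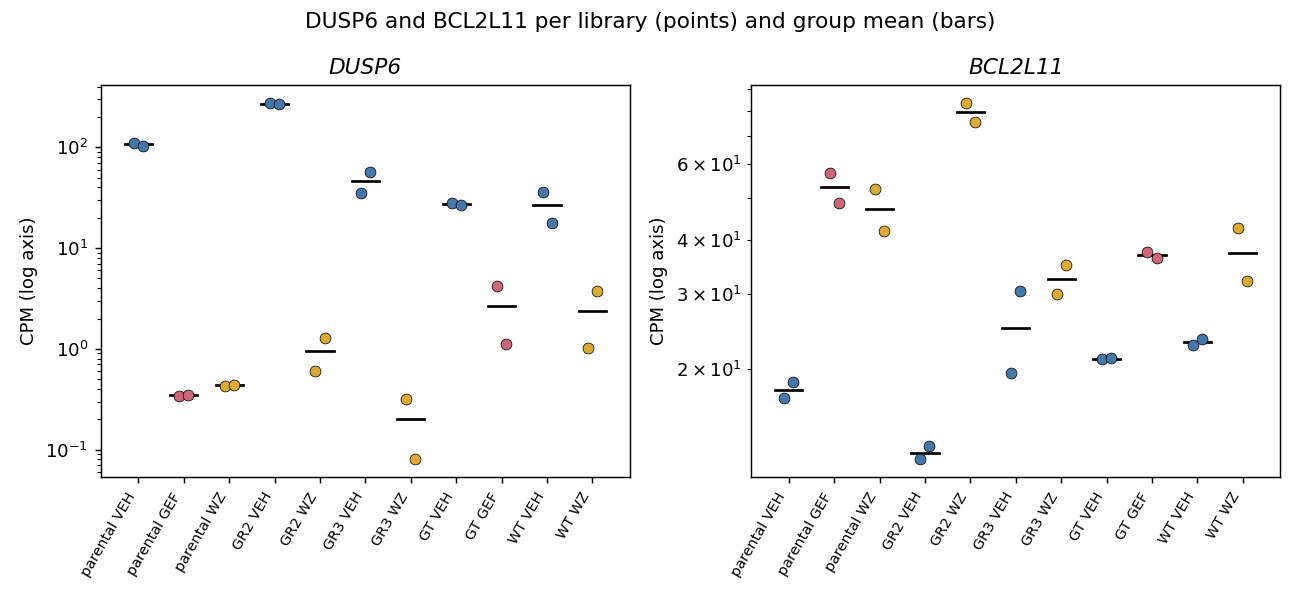
CPM of DUSP6 and BCL2L11 (y axes, log scale) in the 11 groups (x axis), with a point for each library and a bar at each group mean. DUSP6 falls under drug from means of 27.0 to 271 CPM to means of 0.200 to 2.65 CPM, and BCL2L11 reaches 79.4 CPM in WZ4002-treated GR2 cells against 32.4 CPM in WZ4002-treated GR3 cells.

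EGFR itself stood at 606 ± 73.6 CPM in vehicle-treated parental cells, and most of its calls were lost when single libraries were left out. It was higher in vehicle-treated WZ4002-tolerant cells (1371 ± 244 CPM, 1.17 ± 0.24, adjusted p = 0.00396). The rise in GR2 vehicle cells (0.99 ± 0.24, adjusted p = 0.0122) was lost with the column-run term (adjusted p = 0.115) and without the 1st GR2 (adjusted p = 0.112) or the 2nd parental vehicle library (adjusted p = 0.1). That in gefitinib-tolerant vehicle cells (1.06 ± 0.24, adjusted p = 0.00694) was lost without their 1st library (adjusted p = 0.0832) or the 2nd parental one (adjusted p = 0.0659). Under WZ4002 EGFR rose in parental cells by 0.72 ± 0.24 (adjusted p = 0.0241; adjusted p = 0.133 without the 2nd vehicle, 0.228 without the 2nd WZ4002 library, 0.0786 with a spread from the groups compared alone), whereas gefitinib gave 0.53 ± 0.24 (adjusted p = 0.0905). It fell in GR3 cells by -0.97 ± 0.24 (adjusted p = 0.0106; adjusted p = 0.0677 without the 2nd vehicle, 0.122 without the 2nd WZ4002 library, 0.112 from the groups compared alone). It fell in gefitinib-tolerant cells by -0.88 ± 0.24 (adjusted p = 0.0147; adjusted p = 0.155 without the 1st vehicle and 0.178 without the 2nd drug library) and in WZ4002-tolerant cells by -1.07 ± 0.24 (adjusted p = 0.00461; adjusted p = 0.0719 without the 1st vehicle library). In GR2 cells under WZ4002 the difference was -0.10 ± 0.24 (adjusted p = 0.74; 0.09 without the 1st drug library and 0.04 with the column-run term), and GR3 vehicle cells differed from parental ones by 0.54 ± 0.24 (adjusted p = 0.134) and from GR2 ones by -0.45 ± 0.24 (adjusted p = 0.175).

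MCL1, an anti-apoptotic BCL2 family member, rose with gefitinib in parental cells from 130 ± 4.88 to 217 ± 34.4 CPM (0.72 ± 0.13, adjusted p = 0.000406). With WZ4002 the rise was 0.51 ± 0.13 (adjusted p = 0.00447; adjusted p = 0.0588 without the 1st WZ4002 library and 0.0526 from the groups compared alone). The drug responses of the other populations did not pass, at 0.07 ± 0.13 in GR2 cells (-0.23 with the column-run term), -0.13 ± 0.13 in GR3, -0.28 ± 0.13 in gefitinib-tolerant (adjusted p = 0.107; adjusted p = 0.0473 with that term) and -0.28 ± 0.13 in WZ4002-tolerant cells. After vehicle MCL1 was higher in GR2 than in parental cells (0.68 ± 0.13, adjusted p = 0.00237) and lower in GR3 than in GR2 cells (-0.46 ± 0.13, adjusted p = 0.0116; adjusted p = 0.0911 without the 1st GR2 and 0.0575 without the 1st GR3 vehicle library; -0.77 with the column-run term). Against parental cells the differences were 0.21 ± 0.13 in GR3, 0.14 ± 0.13 in gefitinib-tolerant and 0.17 ± 0.13 in WZ4002-tolerant cells, with adjusted p of 0.271, 0.475 and 0.388.

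The vehicle groups show how the populations differed before drug. In GR2 cells COL8A1 was at 180 ± 2.07 CPM against 0.495 ± 0.347 in parental cells (6.94 ± 0.35, adjusted p = 2.02e-08), and IGFN1, an immunoglobulin-like gene, was higher (3.56 ± 0.34). IGFBP5, a secreted IGF-binding protein (-4.47 ± 0.70), RARRES1 (-3.90 ± 0.44), the aldehyde dehydrogenase ALDH3B2 (-3.43 ± 0.31) and PADI4 (-3.43 ± 0.38) were lower. Alveolar genes were lower in 4 of 8 members (4, median -0.79, adjusted p = 0.0064, 0.182 estimated). Without the 1st GR2 or the 2nd parental library 2 were lower. YAP targets were higher in 5 of 10 (6, median 0.76, adjusted p = 0.0358, 0.694 estimated), in 2 without either GR2 library and in 3 without either parental one. Handling stress genes, a list meant to mark sample handling, were lower in 4 of 12 and higher in 1 (5 and 1, median -0.44, adjusted p = 0.0463, 0.667 estimated), and integrated stress response genes were higher in 5 of 12 (7, median 0.75, adjusted p = 0.0307, 0.694 estimated). Both calls were lost without the 2nd parental library (adjusted p = 0.0723 each, 1 member each). Without the 1st and the 2nd GR2 library 1 and 2 handling stress genes were lower and 0 and 1 integrated stress response genes higher, the latter being 3 without the 1st parental library. Cholesterol synthesis genes were lower in 1 of 14 (1, median -0.41, adjusted p = 0.0463, 0.713 estimated), a call lost without any of the 4 libraries (0 members, adjusted p = 0.0552 to 0.0808). DUSP6 was higher by 1.34 ± 0.41 (adjusted p = 0.0372), a call lost without any of the 4 libraries (adjusted p = 0.114 and 0.155 without the 1st and 2nd parental, 0.174 and 0.136 without the 1st and 2nd GR2 library), with the column-run term (adjusted p = 0.396), with a pseudocount of 0.1 (adjusted p = 0.131) and with no filter (adjusted p = 0.0527). BCL2L11 differed by -0.45 ± 0.18 (adjusted p = 0.0963; adjusted p = 0.0274 from the groups compared alone). In all, 2591 genes passed (1390 higher and 1201 lower), 710 by at least 2-fold. The count was 1404 and 1135 without the 1st and the 2nd parental library, 769 and 1043 without the 1st and the 2nd GR2 library, 1449 with the column-run term and 4585 with a spread from these 4 libraries alone. Both GR2 and neither parental library lie in the last of 3 runs of columns, so an effect of that run may enter except as far as the term removes it.

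GR3 vehicle cells differed from parental ones by the near loss of PXDN, an extracellular matrix peroxidase, at 0.160 ± 0.127 against 242 ± 37.2 CPM (-7.71 ± 0.16, adjusted p = 2.09e-14). The keratin KRT13 (-5.88 ± 0.26), the adhesion molecule CEACAM6 (-5.45 ± 0.35) and RARRES1 (-4.14 ± 0.44) were also lower, and the proteoglycan SPOCK1 (4.13 ± 0.40), ALPP (4.10 ± 0.55) and SUSD2 (3.38 ± 0.67) were higher. SLC22A20P, a transporter pseudogene whose reads could come from related genes, was lower by -4.50 ± 0.25. Of 13 mesenchymal genes 5 were higher and 1 lower (5 and 2, median 0.78, adjusted p = 0.00827, 0.315 estimated). The receptor kinase AXL (3.18 ± 0.27), at 135 ± 9.84 against 14.1 ± 2.48 CPM, was among them. DUSP6 was lower by -1.23 ± 0.41 (adjusted p = 0.0451), a call lost without the 1st or the 2nd parental (adjusted p = 0.169 and 0.128) or the 1st GR3 library (adjusted p = 0.226), with a pseudocount of 0.1 (adjusted p = 0.153) and with no filter (adjusted p = 0.0628). BCL2L11 differed by 0.43 ± 0.18 (adjusted p = 0.104; 0.74 with adjusted p = 0.00916 without the 1st GR3 library). The call of glycolysis (adjusted p = 0.00458, 0.851 estimated) was lost without the 2nd GR3 (0.304) or the 1st parental library (0.113). In all, 3228 genes passed (1513 higher and 1715 lower), 987 by at least 2-fold; the count was 1827 and 1926 without the 1st and the 2nd parental library and 1046 with a spread from these 4 libraries alone.

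GR3 and GR2 cells were also compared directly with each other after vehicle. IGFBP5 (6.22 ± 0.70), the adhesion molecule L1CAM (6.10 ± 0.54), SUSD2 (5.51 ± 0.67) and the amine oxidase AOC1 (4.96 ± 0.55) were higher in GR3 cells. PXDN (-6.73 ± 0.16), CEACAM6 (-5.73 ± 0.35), the telomerase gene TERT (-5.29 ± 0.27), COL8A1 (-5.26 ± 0.35) and DUSP6 (-2.57 ± 0.41, adjusted p = 0.000215) were lower. BCL2L11 was higher by 0.88 ± 0.18 (adjusted p = 0.00141), a call lost with the column-run term (0.56, adjusted p = 0.0799) and with a spread from these 4 libraries alone (adjusted p = 0.0549), and 0.58 without the 2nd GR3 library. Of 12 integrated stress response genes 6 were lower (7, median -0.98, adjusted p = 0.0211, 0.561 estimated), including the transcription factor ATF4 (-1.44 ± 0.13), a list call lost without the 1st GR3 library (median -0.42, adjusted p = 0.217), with a median of -1.63 without the 2nd. In all, 5132 genes passed (2415 higher and 2717 lower), 1675 by at least 2-fold, and 2995 and 3285 passed without the 1st and the 2nd GR2 library and 3915 with the column-run term, both GR2 libraries being in the last run.

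Gefitinib-tolerant cells after vehicle carried 1708 ± 925 CPM of FN1, the matrix protein fibronectin, against 20.2 ± 2.45 in parental cells (6.22 ± 0.46, adjusted p = 1.41e-06). SPOCK1 (4.88 ± 0.40), the scavenger receptor OLR1 (4.22 ± 0.48), the matrix protein THBS1 (4.21 ± 0.40) and IGFN1 (4.05 ± 0.34) were higher. The mucin MUC5B (-4.77 ± 0.66), the adenylate cyclase ADCY5 (-4.26 ± 0.33) and ALDH3B2 (-3.74 ± 0.31) were lower. Of 13 mesenchymal genes 7 were higher and 2 lower (8 and 2, median 1.48, adjusted p = 0.000194, 0.0885 estimated), including AXL (3.32 ± 0.27), and 7 of 10 YAP targets were higher (7, median 0.89, adjusted p = 1.47e-05, 0.151 estimated), including ANKRD1 (3.51 ± 0.42). Integrated stress response genes were lower in 9 of 12 members (10, median -1.91, adjusted p = 3.19e-09, 0.133 estimated). DDIT4 (-2.98 ± 0.37), ATF4 (-1.58 ± 0.13) and the serine synthesis enzyme PHGDH (-1.90 ± 0.25) were among them. Cholesterol synthesis genes were lower in 3 of 14 (5, median -0.72, adjusted p = 0.000292, 0.814 estimated) and alveolar genes in 3 of 8 (4, median -0.56, adjusted p = 0.00774, 0.133 estimated). DUSP6 was lower by -1.92 ± 0.41 (adjusted p = 0.00457) and BCL2L11 differed by 0.23 ± 0.18 (adjusted p = 0.411). Calls of other receptor kinases and ligands (adjusted p = 0.0482, 0.431 estimated) and NF-kB and cytokine genes (adjusted p = 0.0241, 0.814 estimated) were lost without the 2nd (0.0619) and the 1st tolerant (0.141) and without the 2nd (0.0759) and the 1st parental library (0.15). In all, 2947 genes passed (1454 higher and 1493 lower), 909 by at least 2-fold, with 1487 and 1554 without the 1st and the 2nd parental library and 1203 without the 1st tolerant one.

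WZ4002-tolerant cells after vehicle had FN1 at 1375 ± 946 CPM (5.83 ± 0.46, adjusted p = 3.12e-06), with SPOCK1 (4.38 ± 0.40), OLR1 (4.09 ± 0.48) and THBS1 (3.82 ± 0.40) higher and ADCY5 (-4.06 ± 0.33), MUC5B (-4.03 ± 0.66), ALDH3B2 (-3.84 ± 0.31) and the carbonic anhydrase CA9 (-3.71 ± 0.43) lower. Mesenchymal genes were higher in 6 of 13 members and lower in 2 (8 and 2, median 1.29, adjusted p = 0.000895, 0.0877 estimated), with a median of 0.80 without the 2nd parental library. Other receptor kinases and ligands were higher in 5 of 10 and lower in 1 (5 and 3, median 0.65, adjusted p = 0.0146, 0.258 estimated), including FGFR1 (1.74 ± 0.20) and the AXL ligand GAS6 (2.83 ± 0.35), and 6 of 10 YAP targets were higher (6, median 0.93, adjusted p = 7.72e-05, 0.215 estimated), including F3 (2.88 ± 0.26). Integrated stress response genes were lower in 9 of 12 (9, median -1.97, adjusted p = 1.48e-09, 0.0877 estimated), cholesterol synthesis genes in 4 of 14 (7, median -0.80, adjusted p = 7.72e-05, 0.651 estimated) and alveolar genes in 4 of 8 (4, median -0.69, adjusted p = 0.00309, 0.0877 estimated). Without any of the 4 libraries 2 cholesterol synthesis genes were lower, and without the 2nd parental library 2 alveolar genes. DUSP6 was lower by -2.03 ± 0.41 (adjusted p = 0.00342; adjusted p = 0.0618 without the 2nd tolerant library) and BCL2L11 differed by 0.36 ± 0.18 (adjusted p = 0.182). Calls of DNA replication (adjusted p = 0.0315, 0.783 estimated) and NF-kB and cytokine genes (adjusted p = 0.00789, 0.651 estimated) were lost without the 1st (0.189) and the 2nd tolerant (0.0644) and without the 2nd (0.395) and the 1st parental library (0.0681). In all, 2856 genes passed (1350 higher and 1506 lower), 858 by at least 2-fold. The count was 1430 and 1453 without the 1st and the 2nd parental library and 1677 and 1300 without the 1st and the 2nd tolerant one.

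**Figure D4:**
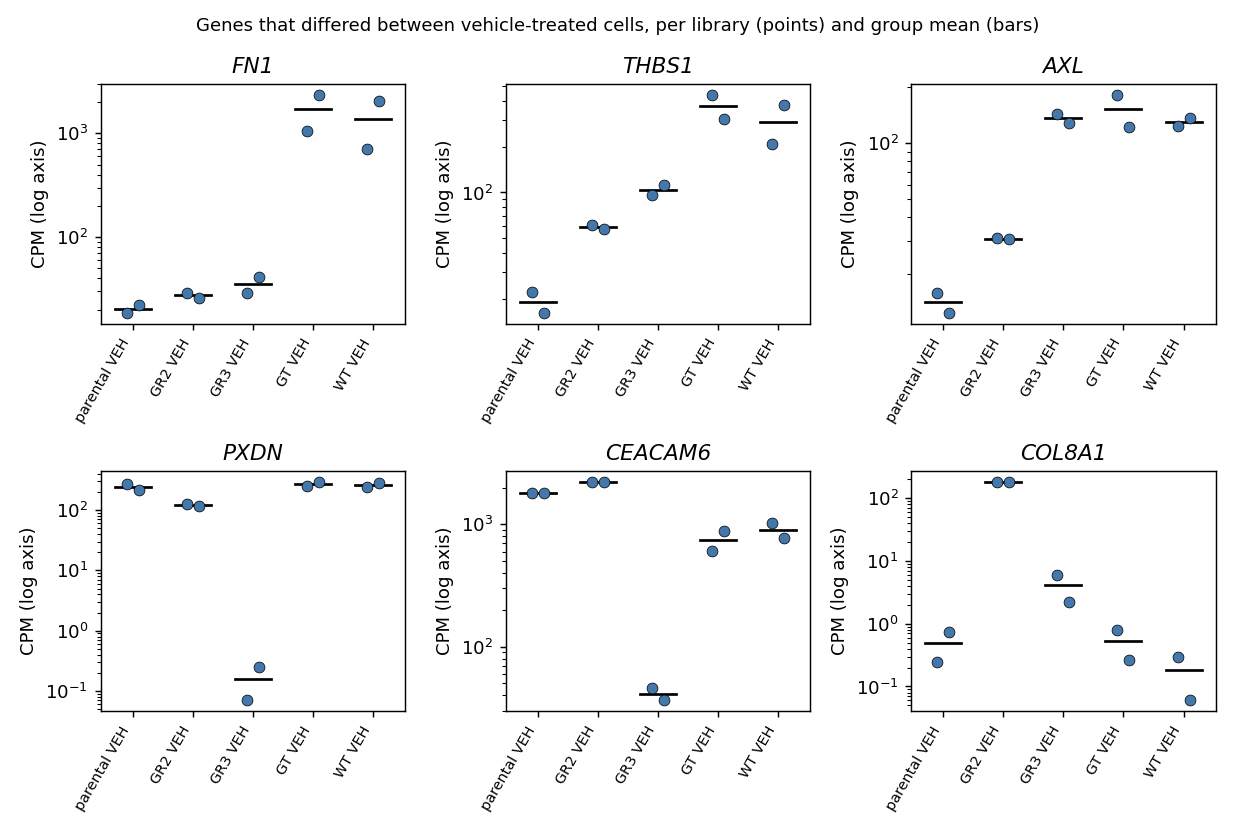
CPM (y axis, log scale) of FN1, THBS1, AXL, PXDN, CEACAM6 and COL8A1 in the 5 vehicle-treated populations (x axis), with a point for each library and a bar at each mean. FN1 has means of 1708 and 1375 CPM in the tolerant populations against 20.2 in parental cells, PXDN has a mean of 0.160 CPM in GR3 cells against 242 in parental cells, and COL8A1 has a mean of 180 CPM in GR2 cells against 0.495.

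The tolerant populations were compared with each other after vehicle to ask whether the inhibitor used to obtain them was reflected in their transcripts. FN1 differed by -0.39 (95% interval -1.36 to 0.57, WZ4002-tolerant minus gefitinib-tolerant), EGFR by 0.11 (-0.41 to 0.63), DUSP6 by -0.10 (-0.98 to 0.78), BCL2L11 by 0.12 (-0.26 to 0.51), MCL1 by 0.03 (-0.25 to 0.30) and ATF4 by 0.22 (-0.06 to 0.50). The sign turned for EGFR without the 2nd gefitinib-tolerant (-0.04) or the 1st WZ4002-tolerant library (-0.07), for MCL1 without the latter (-0.02) and for DUSP6 without the 2nd WZ4002-tolerant library (0.40). By limma 0 genes passed, 132 had an unadjusted p under 0.05, limma-voom called 0, and 1 gene passed without the 2nd WZ4002-tolerant library. No list passed, the lowest adjusted p being 0.341. The interval excluded a log2 difference of 1 for 95.6% of genes. Low genes may differ more in fold, and likeness was not shown.

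Whether GR3 cells departed from GR2 cells in the direction in which tolerant cells departed from parental ones was tested across 15485 genes, in comparisons that share no library. Across genes, which are not independent replicates, Pearson's r was 0.069 and Spearman's rho 0.046 (covariance 0.0265) with gefitinib-tolerant cells, and 0.043 and 0.015 (covariance 0.0160) with WZ4002-tolerant cells. With gefitinib-tolerant cells r was -1e-04 without the 1st and 0.135 without the 2nd vehicle-treated GR3 library, and 0.127 with the column-run term. With WZ4002-tolerant cells it was -0.03, 0.116 and 0.0917 in the same settings. Of the called genes, 335 were higher and 459 lower both in GR3 and in gefitinib-tolerant cells, where independent lists would share 226.8 and 262.0, and 245 and 320 went opposite ways against 232.8 and 255.1. For WZ4002-tolerant cells 277 were higher and 427 lower in both, against 210.5 and 264.2, and 276 and 305 went opposite ways against 234.9 and 236.9. The genes lower in gefitinib-tolerant cells had a median of -0.14 in GR3 against GR2 cells (adjusted p = 0.0233, 0.736 estimated), and the genes higher in them did not pass (median 0.02, adjusted p = 0.485). For WZ4002-tolerant cells neither the genes lower (median -0.09, adjusted p = 0.24) nor those higher (median -0.02, adjusted p = 0.981) passed.

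Drug responses of different populations were tested by their difference. GR2 and parental cells differed under WZ4002 in 1051 genes (517 higher and 534 lower). GR3 and parental cells differed in 200 genes (98 and 102). GR3 and GR2 cells differed in 2103 (1050 and 1053). TERT (5.22 ± 0.39) was among them. TERT fell from 58.5 ± 0.552 to 0.0750 ± 0.00707 CPM in GR2 cells and stood at 0.525 ± 0.0495 before and 0.0250 ± 0.00707 after drug in GR3 cells, so the difference came from its level in vehicle-treated GR2 cells. The gefitinib response of gefitinib-tolerant and parental cells differed in 310 genes (165 and 145), and the WZ4002 response of WZ4002-tolerant and parental cells in 696 (325 and 371). ASNS led both, at 4.43 ± 0.60 and 4.43 ± 0.60 (adjusted p = 0.00165 and 0.00131). It fell from 91.5 ± 17.4 to 4.61 ± 0.177 CPM with gefitinib in parental cells and stood at 12.5 ± 1.85 before and 16.8 ± 2.38 after it in gefitinib-tolerant cells. Each of these 5 counts moved by over 1.5 times when single libraries were left out, with values given below.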

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

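All tests of explanations here were chosen after the results were seen. Each result below was set aside because a drug response differed between populations when tested directly. List values are median log2 differences with camera adjusted p at the preset and the estimated correlation, and a library is named where leaving it out ended the call or moved a called value by over 1.5 times.

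BCL2L11 rose less under WZ4002 in GR3 than in GR2 cells, by -2.15 ± 0.25. A single deviating library would end the call when left out, and the highest adjusted p over the 8 libraries was 0.000994, with differences of -2.46 to -1.85. Median-of-ratios scaling gave adjusted p = 7.69e-05, but its factors lay within 3% of 1, so that test moved little and decides nothing about scaling. Both GR2 vehicle libraries lie in the last of 3 runs of columns, and with the column-run term the difference was -1.83 with an adjusted p below 0.001. A weaker drug effect on ERK output in GR3 cells remains open: after WZ4002 the ERK output list differed by a median of 0.13 with 10 of 18 genes above 0, and transcripts alone may not show pathway activity. Protein levels of BIM were not analysed here.

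ERK output genes fell less under drug in tolerant than in parental cells, by 1.09 with gefitinib (5 of 18 members, 12 higher and 1 lower adjusted over the list alone, adjusted p = 3.2e-08, 0.323 estimated; 2 and 0 members without the 1st parental gefitinib and vehicle, 1 and 3 without the 1st tolerant gefitinib and the 2nd tolerant vehicle library) and by 1.35 with WZ4002 (6 members, 8 over the list alone, adjusted p = 1.16e-09, 0.247 estimated). A lower starting level alone would leave equal levels after drug. Drug-treated WZ4002-tolerant cells stood higher by 1.259 (fry adjusted p = 0.00515 and at most 0.0474 without a library, camera adjusted p = 0.422 with an estimated correlation; 0.65 without the 2nd tolerant WZ4002 library), which argues against it there. Gefitinib-tolerant cells stood higher by 1.015 (fry adjusted p = 0.0172, camera adjusted p = 0.456 with an estimated correlation), but the fry adjusted p was 0.0622 and 0.0715 without the 1st and the 2nd parental gefitinib and 0.133 without the 1st tolerant gefitinib library (0.64), so for them it cannot be told apart from a smaller fall. No single library set the smaller fall, the highest adjusted p over both being 3.15e-05. The values are consistent with residual ERK output under drug in WZ4002-tolerant cells, but incomplete inhibition, other inputs to ERK and a mixture of cells could each give them and were not told apart.

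GR2 and parental cells differed in their WZ4002 response in 1051 genes (604 and 550 without the 1st and the 2nd parental vehicle library, 328 and 449 without the 1st and the 2nd GR2 vehicle library, 693 and 484 without the 1st and the 2nd GR2 WZ4002 library, 338 with the column-run term). Both GR2 vehicle libraries lie in the last run of columns, so part of these differences may come from that run. CAPN13 (4.70 ± 0.58), the alarmin S100A8 (4.02 ± 0.52), COL8A1 (-5.91 ± 0.49) and ANXA1 (-4.52 ± 0.65) led, with CDK14 at -3.63 ± 0.43 (-5.51 with a pseudocount of 0.1, -5.87 by limma-voom) and VTCN1 at 4.04 ± 0.75 (3.31 with adjusted p = 0.152 with the column-run term). COL8A1 was hardly detected in vehicle-treated parental cells and could fall little there. Its difference therefore came from its level in vehicle-treated GR2 cells. BCL2L11 rose more in GR2 cells, by 1.19 ± 0.25 (adjusted p = 0.279 with the column-run term, 0.0594 without the 1st GR2 vehicle library). YAP targets differed by -0.85 (3 of 10 members, 4 over the list alone, adjusted p = 0.00329, 0.454 estimated; 1 member without the 2nd parental vehicle or any of the 4 GR2 libraries) and alveolar genes by 0.73 (2 of 8 members, 2 over the list alone, adjusted p = 0.00611, 0.251 estimated; 0.48 without the 2nd parental vehicle and 0.41 without the 2nd parental WZ4002 library). Cholesterol synthesis differed by 0.97 (0 of 14 members, adjusted p = 0.00169, 0.494 estimated; 1.63 with 11 members without the 1st and 0.23 with adjusted p = 0.318 without the 2nd parental WZ4002 library).

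GR3 and parental cells differed in 200 genes (46 and 124 without the 1st and the 2nd parental vehicle library, 703 without the 1st parental WZ4002 library, 1059 and 122 without the 1st and the 2nd GR3 vehicle library, 79 without the 2nd GR3 WZ4002 library). SLC22A20P differed by 3.10 ± 0.35, IL1RL1 by 2.89 ± 0.37 (adjusted p = 0.257 by limma-voom), the hyaluronidase CEMIP by 2.77 ± 0.51 (adjusted p = 0.133 from the groups compared alone, 0.0832 without the 1st parental vehicle library), TPPP3 by -3.83 ± 0.44 (adjusted p = 0.183 by limma-voom) and TPPP by -3.59 ± 0.43 (adjusted p = 0.0672 from the groups compared alone). ALPP differed by -3.51 ± 0.77, a call lost by limma-voom (adjusted p = 0.0506), with no filter (0.0532), from the groups compared alone (0.316) and without the 2nd GR3 vehicle (0.147), the 1st or the 2nd GR3 WZ4002 (0.0905, 0.0845), the 1st parental vehicle (0.167) or the 2nd parental WZ4002 library (0.118). EGFR differed by -1.69 ± 0.35 (adjusted p = 0.0259), a call lost from the groups compared alone (0.246) and without the 2nd GR3 vehicle (0.0969), the 2nd GR3 WZ4002 (0.101), the 1st or the 2nd parental vehicle (0.0832, 0.0723) or the 2nd parental WZ4002 library (0.0866).

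By list, GR3 and parental responses differed in DNA replication by 1.21 (0 of 21 members, adjusted p = 2.12e-07, 0.666 estimated; 2.03 with 15 members and 0.49 without the 1st and the 2nd GR3 vehicle library), in glycolysis by 0.74 (0 of 14 members, 8 over the list alone, adjusted p = 1.61e-05, 0.666 estimated; 1.21 with 8 members and 0.38 without the same libraries, 1 and 2 members without the 2nd parental vehicle and the 1st parental WZ4002 library) and in squamous and neuroendocrine genes by -0.91 (1 of 6 members, 3 over the list alone, adjusted p = 0.00322, 0.102 estimated; -0.56 without the 2nd GR3 vehicle library, 2 members without the 1st, 3 and 2 without the 1st and the 2nd parental WZ4002 library). Cholesterol synthesis differed by 0.74 (adjusted p = 0.00192, 0.842 estimated; 1.24 without the 1st GR3 vehicle, 1.497 without the 1st parental WZ4002, adjusted p = 0.207 without the 2nd GR3 vehicle and 0.858 without the 2nd parental WZ4002 library). EGFR family and ligands differed by -0.45 (adjusted p = 0.047, 0.666 estimated; adjusted p = 0.456 without the 2nd GR3 vehicle, 0.0934 without the 1st GR3 WZ4002, 0.0608 and 0.0704 without the 1st and the 2nd parental vehicle, 0.236 without the 2nd parental WZ4002 library). FOXO targets differed by -0.43 (adjusted p = 0.0238, 0.666 estimated; -0.26 without the 1st parental vehicle, adjusted p = 0.104 without the 2nd GR3 vehicle, 0.0664 without the 1st GR3 WZ4002, 0.0677 without the 2nd parental vehicle, 0.168 without the 2nd parental WZ4002 library). Mitosis differed by 0.84 (adjusted p = 0.0387, 0.842 estimated; adjusted p = 0.808 without the 2nd GR3 vehicle, 0.317 without the 1st parental vehicle, -0.05 with adjusted p = 0.903 without the 1st GR3 WZ4002, -0.05 with adjusted p = 0.919 without the 1st parental WZ4002, 1.405 without the 1st GR3 vehicle, 1.64 without the 2nd GR3 WZ4002 and 1.68 without the 2nd parental WZ4002 library).

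GR3 and GR2 cells differed in 2103 genes (1005 and 1151 without the 1st and the 2nd GR2 vehicle library, 1148 without the 2nd GR2 WZ4002 library, 2073 with the column-run term, which bears on the GR2 vehicle libraries of the last run). COL8A1 (5.33 ± 0.49), TERT (5.22 ± 0.39), VTCN1 (-4.66 ± 0.75), PIGR (-4.56 ± 0.45) and ALPP (-4.54 ± 0.77) led, with the calcium-binding CALB1 at 5.76 ± 1.42 (adjusted p = 0.0501 without the 1st GR2 vehicle and 0.0584 without the 2nd GR3 WZ4002 library). DUSP6 differed by 1.89 ± 0.59 (adjusted p = 0.0426), a call lost with the column-run term (adjusted p = 0.206), by limma-voom (0.24, adjusted p = 0.924), with a pseudocount of 0.1 (0.75, adjusted p = 0.587), with no filter (adjusted p = 0.0609) and without the 1st or the 2nd GR2 vehicle (0.12, 0.104), the 1st or the 2nd GR2 WZ4002 (0.128, 0.0622), the 1st GR3 vehicle (0.105) or the 1st or the 2nd GR3 WZ4002 library (0.115, 0.0694). Alveolar genes differed by -0.99 (3 of 8 members, 4 over the list alone, adjusted p = 0.00302, 0.177 estimated). DNA replication differed by 1.36 (3 of 21 members, 10 over the list alone, adjusted p = 0.000511, 0.552 estimated; 2.19 with 16 members without the 1st and adjusted p = 0.0882 with 0 without the 2nd GR3 vehicle library) and glycolysis by 0.68 (4 of 14, 7 over the list alone, adjusted p = 0.0123, 0.552 estimated; 1.09 with 10 members and adjusted p = 0.144 with 0 without the same libraries). Without the 1st and the 2nd GR2 vehicle, the 2nd GR2 WZ4002 and the 1st GR3 WZ4002 library 0, 1, 0 and 1 DNA replication and 1, 0, 0 and 2 glycolysis genes passed, and 1 glycolysis gene without the 2nd GR3 WZ4002 library. YAP targets differed by 0.73 (adjusted p = 0.0354, 0.552 estimated; adjusted p = 0.0743 without the 1st GR2 WZ4002, 0.12 without the 1st GR3 vehicle, 0.147 without the 2nd GR3 WZ4002 library) and FOXO targets by -0.53 (adjusted p = 0.0491, 0.552 estimated; adjusted p = 0.0516 without the 2nd GR2 vehicle, 0.0724 without the 1st GR2 WZ4002, 0.0882 without the 2nd GR3 vehicle, 0.0952 without the 1st GR3 WZ4002 library).

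Gefitinib-tolerant and parental cells differed in their gefitinib response in 310 genes (90 and 198 without the 1st and the 2nd parental vehicle library, 93 and 194 without the 1st and the 2nd parental gefitinib library, 111 and 147 without the 1st and the 2nd tolerant vehicle library, 114 without the 1st tolerant gefitinib library). ASNS (4.43 ± 0.60) and the glutathione-degrading CHAC1 (3.40 ± 0.51) led, with the peptide hormone ADM2 at 3.77 ± 0.67 (adjusted p = 0.0701 by limma-voom), SEMA5B at -3.52 ± 0.59 (adjusted p = 0.551 by limma-voom) and the KIT ligand KITLG at -3.39 ± 0.61 (adjusted p = 0.0554 without the 1st parental gefitinib and 0.0562 without the 1st parental vehicle library). KRT4 differed by -3.54 ± 0.77, a call lost by limma-voom (-1.77, adjusted p = 0.713), with a pseudocount of 0.1 (-2.21, adjusted p = 0.261) and without the 1st or the 2nd parental gefitinib (0.101, 0.0618), the 1st tolerant gefitinib (0.131), the 1st or the 2nd tolerant vehicle (0.084, 0.0818) or the 1st parental vehicle library (0.136). DUSP6 differed by 3.22 ± 0.59 (adjusted p = 0.0101; adjusted p = 0.0759 by limma-voom, 0.0506 without the 1st tolerant gefitinib and 0.051 without the 1st parental vehicle library) and MCL1 by -1.01 ± 0.18 (adjusted p = 0.01; adjusted p = 0.0619 without the 1st parental gefitinib library). EGFR differed by -1.41 ± 0.35 (adjusted p = 0.0478), a call lost by limma-voom (0.059), with median-of-ratios scaling (0.0531), with no filter (0.0763) and without any of the 8 libraries, in the order 1st and 2nd of parental vehicle (0.104, 0.126), parental gefitinib (0.202, 0.0518), tolerant vehicle (0.17, 0.0818) and tolerant gefitinib (0.0703, 0.128). By list, the integrated stress response differed by 1.62 (6 of 12 members, 9 over the list alone, adjusted p = 3.41e-11, 0.0557 estimated), DNA replication by 1.42 (2 of 21, 13 over the list alone, adjusted p = 7.05e-11, 0.394 estimated), mitosis by 1.89 (0 of 20, adjusted p = 3.51e-08, 0.576 estimated) and epithelial genes by -0.48 (2 of 15, 7 over the list alone, adjusted p = 7.02e-05, 0.0557 estimated). Squamous and neuroendocrine genes differed by -1.54 (3 of 6, 4 over the list alone, adjusted p = 1.6e-05, 0.0129 estimated). Integrated stress response counts were 3 without the 1st library of any of the 4 groups. DNA replication counts were 0 without these or the 2nd tolerant vehicle library and 1 without the 2nd parental gefitinib library. Epithelial counts were 1 without any library but the 2nd parental gefitinib one, and squamous and neuroendocrine counts 1 without any but the 1st parental gefitinib and the 2nd tolerant vehicle library.

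WZ4002-tolerant and parental cells differed in their WZ4002 response in 696 genes (222 without the 1st parental vehicle, 1076 without the 1st parental WZ4002, 274 without the 1st tolerant vehicle and 174 without the 2nd tolerant WZ4002 library). ASNS (4.43 ± 0.60), ADM2 (3.97 ± 0.67), ETV5 (3.56 ± 0.54) and TNFSF10 (-4.04 ± 0.53) led, with KRT4 at -4.29 ± 0.77 (adjusted p = 0.113 by limma-voom). AGXT differed by -4.19 ± 0.89, a call lost by limma-voom (adjusted p = 0.43), from the groups compared alone (0.103) and without the 1st parental vehicle (0.0731), the 1st tolerant vehicle (0.0582) or the 2nd tolerant WZ4002 library (0.0898), and -2.68 without the 2nd parental WZ4002 library. EGFR differed by -1.79 ± 0.35 (adjusted p = 0.00957; adjusted p = 0.0501 without the 2nd tolerant WZ4002 library) and DUSP6 by 3.14 ± 0.59 (adjusted p = 0.00835; adjusted p = 0.0501 without the same library). MCL1 differed by -0.79 ± 0.18 (adjusted p = 0.023), a call lost from the groups compared alone (0.12) and without the 1st or the 2nd parental vehicle (0.0689, 0.0691), the 1st parental WZ4002 (0.0547), the 1st tolerant vehicle (0.0893) or the 2nd tolerant WZ4002 library (0.123).

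By list, the WZ4002 response of WZ4002-tolerant cells differed from that of parental cells in the integrated stress response by 2.53 (9 of 12 members, 11 over the list alone, adjusted p = 1.11e-12, 0.0574 estimated; 5 members without the 1st parental vehicle or the 2nd parental WZ4002 library, 6 without either tolerant vehicle or the 2nd tolerant WZ4002 library), in DNA replication by 1.12 (1 of 21, 1 over the list alone, adjusted p = 6.65e-05, 0.682 estimated; 0.73 without the 1st parental WZ4002 library, 2 members without the 2nd parental vehicle and 0 without any other library but the 1st tolerant WZ4002 one) and in squamous and neuroendocrine genes by -1.09 (3 of 6, 3 over the list alone, adjusted p = 0.000639, 0.0487 estimated). Mitosis differed by 1.07 (adjusted p = 0.0067, 0.736 estimated; adjusted p = 0.0558 without the 1st parental vehicle and 0.702 without the 1st parental WZ4002 library, 1.94 without the 2nd), epithelial genes by -0.36 (adjusted p = 0.0104, 0.247 estimated; -0.23 without the 2nd tolerant vehicle, adjusted p = 0.0782 without the 2nd parental WZ4002 library) and glycolysis by 0.61 (adjusted p = 0.00915, 0.682 estimated; adjusted p = 0.119 without the 1st parental vehicle, 0.0836 without the 2nd tolerant vehicle, 0.0664 without the 2nd parental WZ4002 library). The pro-apoptotic BCL2 family differed by 0.54 (adjusted p = 0.0341, 0.298 estimated; adjusted p = 0.0809 without the 2nd parental vehicle, 0.14 without the 1st tolerant vehicle, 0.0552 without the 2nd tolerant WZ4002, 0.0555 and 0.0782 without the 1st and the 2nd parental WZ4002 library). Other receptor kinases and ligands differed by -0.49 (adjusted p = 0.0341, 0.361 estimated; adjusted p = 0.151 without the 2nd parental vehicle, 0.0836 without the 2nd tolerant vehicle, 0.0599 without the 2nd tolerant WZ4002, 0.191 without the 2nd parental WZ4002 library). NF-kB and cytokine genes differed by 0.59 (adjusted p = 0.0154, 0.682 estimated; adjusted p = 0.0885 without the 2nd parental vehicle, 0.173 without the 1st tolerant vehicle, 0.0552 without the 2nd tolerant WZ4002 library).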

How the results depend on the processing

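Only limma-voom, the column-run term and the leave-out list tests were chosen after the results were seen. Of 5900 results for genes mostly named from these data, a choice that favours kept calls, 5413 kept direction and side of the threshold. Of the others 461 lost a call, 11 gained one and 15 reversed. Causes of moved values were not tested, but fewer libraries lower the counts of most comparisons. With 2 libraries per group a lone sample is assumed to vary like the other groups, and low genes are limited by depth. Neither edgeR nor DESeq2 was run, and limma-voom was the only alternative based on counts.

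With the replicate block GR3 minus parental gave 344 genes, and no other count moved by over 1.5 times; the replicate differences of 55 pairs of groups correlated at -0.55 to 0.72, 23 of them over 0.1, so not every pair passed and the numbers were not used as pairs. GR3 minus parental gave 124 with a pseudocount of 0.1, 84 by limma-voom (DUSP6 -0.054) and 9 from the groups compared alone. Gefitinib-tolerant minus parental gave 167 by limma-voom, 873 with the column-run term and 690 from the groups alone, WZ4002-tolerant minus parental 1479 and 218 with the latter 2. The term gave 1449 for GR2 against parental and 338 for GR2 minus parental, and reversed DUSP6 (-0.124, WZ4002 against gefitinib), EGFR (0.039) and MCL1 (-0.233) in the GR2 response and MCL1 in GR3 minus GR2 (0.105). The groups alone gave 693 for the GR3 response, 4585 for GR2 and 1046 for GR3 against parental. The relation of GR3 minus GR2 with gefitinib-tolerant and WZ4002-tolerant minus parental was 0.1273 and 0.0917 with the term. With an estimated correlation 2 list calls remained of 109.

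Leave-one-out ranges were: parental gefitinib 4525 to 5898, parental WZ4002 4840 to 6409, WZ4002 against gefitinib 0 to 343, GR2 response 6596 to 7255, GR3 response 1729 to 3688, gefitinib-tolerant 976 to 4233, WZ4002-tolerant 1401 to 4184; against parental after vehicle GR2 769 to 1404, GR3 1827 to 3168, gefitinib-tolerant 1203 to 2086, WZ4002-tolerant 1300 to 1677; GR3 against GR2 2995 to 4732, tolerant populations 0 to 1; minus parental GR2 328 to 1266, GR3 46 to 1059, gefitinib-tolerant 90 to 254, WZ4002-tolerant 174 to 1076, GR3 minus GR2 1005 to 2888. The relation ran from -1e-04 to 0.1348 (gefitinib-tolerant) and from -0.0306 to 0.1159 (WZ4002-tolerant). Reversed genes ran, in WZ4002 against gefitinib, from -0.081 to 0.465 for EGFR (-0.027 without the 2nd gefitinib library), -0.113 to 1.936 for CDK1, -0.303 to 1.94 for TOP2A and -0.3 to 1.768 for MKI67. EGFR ran from -0.299 to 0.093 in the GR2 response. Between the tolerant populations EGFR ran from -0.072 to 0.292, DUSP6 from -0.601 to 0.395 and MCL1 from -0.015 to 0.065.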

Other observations

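The comparisons in this part were chosen after the data were seen. After gefitinib, gefitinib-tolerant and parental cells differed in 4942 genes (2521 higher and 2421 lower; 3003 and 3193 without the 1st and the 2nd parental and 2625 without the 1st tolerant gefitinib library). DNA replication genes were higher in 19 of 21 members (median 1.68, adjusted p = 7.44e-10) and mitosis genes in 18 of 20 (median 2.02, adjusted p = 4.77e-06), whereas all 14 cholesterol synthesis genes (median -1.24, adjusted p = 8.71e-06), 9 of 15 epithelial genes (median -0.57, adjusted p = 0.000324) and 5 of 6 squamous and neuroendocrine genes (median -1.58, adjusted p = 0.00128) were lower. Without the 2nd parental or the 1st tolerant gefitinib library 1 mitosis gene passed. Cholesterol synthesis counts were 7 and 5 without the 1st and the 2nd parental and 4 and 7 without the 1st and the 2nd tolerant gefitinib library. The adjusted p of these 5 lists was 0.0798 to 0.456 with an estimated correlation. After WZ4002, WZ4002-tolerant and parental cells differed in 5675 genes (2733 higher and 2942 lower; 3015 without the 2nd tolerant WZ4002 library), with 17 of 21 DNA replication genes (median 1.60, adjusted p = 1.87e-06, 0.422 estimated) and 10 of 12 NF-kB and cytokine genes (median 1.34, adjusted p = 1.99e-05, 0.345 estimated) higher. Without the 2nd tolerant and the 1st parental WZ4002 library 8 and 10 DNA replication genes passed.

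After WZ4002, GR2 and parental cells differed in 877 genes (433 higher and 444 lower; 425 and 312 without the 1st and the 2nd GR2 WZ4002 library), and 0 of 21 DNA replication genes passed (median 0.12). GR3 cells after WZ4002 differed from parental ones in 4596 genes (2213 higher and 2383 lower) and from GR2 ones in 5179 (2509 higher and 2670 lower; 3258 without the 2nd GR2 WZ4002 library). DNA replication genes were higher in GR3 than in parental cells in 10 of 21 members (median 1.08, adjusted p = 0.00101, 0.833 estimated; 0 and 1 members without the 1st GR3 and the 1st parental WZ4002 library), while ERK output genes had a median of 0.04 (adjusted p = 0.868).

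The differences between the libraries of a pair went the same way in several groups. The hypothesis that libraries were handled in runs that follow the order of the columns in the table was tested with the 8 groups whose libraries are split over the first 2 of 3 runs of columns. Of the 165 possible sets of 8 of the 11 groups, 1, the real set, had so high a mean correlation between groups (0.271 against at most 0.226), and 25 of its 28 pairs of groups were above 0. This is consistent with runs that follow the column order, but the labels name no run and the set was looked for after the correlations were seen. Cultures at different points of the drug response could also give such differences: the median absolute correlation of a group's difference with a drug response of other groups was 0.342, which leaves that explanation open.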
